A study of Homo sapiens with 47 samples.

How the data were processed

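The series holds 47 samples of PC3 cells, an established human prostate cancer cell line, that overexpress DDC or SLC6A4 or carry the empty vector. RNA sequencing covered 9 samples, 3 of each line. ChIP sequencing covered 27 samples, with an antibody against H3K4me3, an antibody against H3K4me3Q5ser (the same trimethylated tail with serotonin on its neighbouring glutamine) and an input, 3 of each per line. CUT&Tag, a tagmentation assay of antibody-bound chromatin, covered 11 samples. Samples were grouped by overexpressed gene, assay and antibody as the labels give them, and replicate numbers were taken as numbers only.

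The RNA tables hold DESeq2-normalised signal per gene, which is reads per gene divided by a size factor of the pair of groups, per the file headers. Their log2 fold changes, Wald scores and p-values came from the authors' DESeq2 run and were used only for comparison. Alignment used HISAT2 2.1.0 on GRCh38, per the submitters' processing notes. In all 9 RNA libraries 100% of the deposited values were whole multiples of 1 step per library within a tolerance of 1e-06, so reads per gene could be recovered, and 0 genes differed for an empty-vector library between the pair of tables. The ChIP table holds estimated counts, read pairs per region counted by featureCounts 2.0.3 with fractional sharing of multiple hits, per the file headers. Its command line, per the file headers, carried a strand setting beside regions with no strand. Of its cells 9.78% are not whole, and the estimated counts were rounded before testing. The CUT&Tag table holds CPM per peak, with no library total, as deposited. Peak lists hold start and end positions with no score, and came from MACS2 per the submitters' processing notes; how lists were combined or called up is not stated there.

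The design fixed before the data were examined assumed counts for RNA and named limma on log2(value + 1) for normalised values. The RNA comparisons therefore used limma 3.58.1 with an empirical Bayes trend on log2(normalised value + 1), in R 4.3.3, for genes with at least 10 in at least 3 libraries. Fold changes on this scale understate the change of low genes. The comparison of DDC with SLC6A4 used limma on the recovered reads of all 9 libraries with shared size factors; the design had asked for raw counts there. ChIP comparisons used the quasi-likelihood F-test of edgeR 4.0.16 with TMM scaling over the 19535 regions and edgeR's filter on low counts, and an interaction of mark and line tested the serotonylated mark relative to H3K4me3. DESeq2 1.42.0 was run as an alternative. All p-values are two-sided and Benjamini-Hochberg adjusted within a comparison, with a threshold of 0.05; a second count also asks for an absolute log2 fold change of at least 1, called 2-fold.

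Gene lists were tested with camera (limma), which compares a list with the other genes, at a preset correlation of 0.01, and again with an estimated correlation. fry (limma), which tests a list against no change, was run as an alternative. The design named log2 CPM there; log2(normalised value + 1) was used, with TMM-scaled log2 CPM as an alternative. In all, 22 lists were fixed beforehand: neuroendocrine markers, neural and lineage-plasticity transcription factors, the androgen receptor program, luminal and basal epithelial markers, mesenchymal markers, serotonin and tryptophan handling, transglutaminases with the H3K4 methylation machinery, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis, the ATF4 stress response, the endoplasmic reticulum unfolded protein response, interferon response, NF-kB and cytokines, hypoxia and glycolysis, immediate early genes, NRF2 oxidative stress, metallothioneins, mitochondrial-encoded transcripts, cytosolic ribosomal proteins, and genes of other cell types. The last had too few measured members for a test. DDC and SLC6A4 belong to no list. Genes were named by a rule fixed beforehand: DDC, SLC6A4 and TGM2; per comparison the 8 largest rises and 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and all 3 libraries of one group above all 3 of the other; and up to 3 called members of each list by adjusted p. For ChIP the rule took up to 4 regions up and 4 down with the smallest adjusted p, and the promoters of the named genes.

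GENCODE version 44 gave gene positions; 62625 of 62703 gene identifiers matched. Among the listed genes, 20966 carry no name, and they hold 4.65% to 4.98% of the reads. A gene was assigned a region within 1000 bp of its transcription start. Region GC content came from the GRCh38 sequence. The overlap of the DDC and SLC6A4 calls was set against 50 simulations of unchanged groups sharing the empty-vector libraries and against 100 regroupings of the 9 libraries. Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Intervals on shares of peaks are Wilson intervals at 95%, and those on ratios of reads are exact; they cover counting error only, since reads are not independent molecules.

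The RNA tests of DDC and of SLC6A4 against the empty vector and the DDC tests of both marks were tried on simulated data with 200 changed genes or regions; the other tests were not. For DDC against the empty vector, limma recovered 25.4% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls among 13304 genes. For SLC6A4 it recovered 23.9%, 86.6% and 100%, with 8 false calls among 13449 genes. For H3K4me3Q5ser with DDC, edgeR recovered 41.8%, 89.6% and 100% of regions at these folds, and for H3K4me3 with DDC 28.4%, 91.0% and 100%. The simulated ChIP replicates were given a fixed spread well beyond counting noise. Real ChIP replicates differed by little more than sampling noise (ratios of spread to noise 0.992 to 1.14). The ChIP shares are therefore not estimates of recovery in the real data.

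Depth ranged from 17.3 M to 21.7 M reads in genes per RNA library. Read pairs in the regions came to 13.5 M to 24.8 M for H3K4me3Q5ser, 3.43 M to 5.81 M for H3K4me3 and 1.39 M to 1.83 M for the input. Among 24 pairs of ChIP replicates, 7 differed by no more than sampling noise; such pairs were counted once when means and SDs were formed, which leaves n = 2 for each group but H3K4me3Q5ser with DDC and the input of the empty vector, where n = 3. Alternatives covered other tools, scaling, filters, a replicate block and each library left out in turn. Chosen after seeing the data were edgeR on the recovered reads, other pseudocounts, TMM for the lists, counting near-identical ChIP replicates once, removal of each ChIP library's GC trend and removal of the regional input ratio. So were the block and the left-out libraries for the lists, for the overlap of calls and for RNA at marked genes, and the scaling of the CUT&Tag values to the listed peaks. The SLC6A4 input libraries and 8 CUT&Tag samples, among them those treated with the transglutaminase inhibitor TG2-IN-1, are not analysed here.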

Results

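PC3 cells that overexpress DDC or SLC6A4 were compared with PC3 cells carrying the empty vector. DDC is the decarboxylase that forms serotonin and dopamine, and SLC6A4 is the serotonin transporter. The series title concerns serotonylation of histones and the plasticity of neuroendocrine prostate cancer; serotonin beside trimethylated lysine of histone H3 (H3K4me3Q5ser) can be placed by transglutaminase TGM2. RNA was measured in 3 libraries of each line, with 17.3 M to 21.7 M reads in genes per library. ChIP of H3K4me3Q5ser and of H3K4me3 was counted over 19535 regions (median length 4023 bp) in 3 libraries of each line, at 13.5 M to 24.8 M and 3.43 M to 5.81 M read pairs in regions. CUT&Tag values of H3K4me3 covered 3 libraries with no replicates, 1 each of control cells, SLC6A4 cells and SLC6A4 cells with TGM2 knocked down. On the first principal component of RNA (51.4% of the variance) the empty-vector libraries lay apart from both lines, and the second separated DDC from SLC6A4.

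The question of the first comparison was what DDC overexpression changed in RNA. The DDC gene itself (ENSG00000132437, chromosome 7: 50458436 to 50565405, GRCh38) had 79 reads over the 3 DDC libraries and 1 read over the 3 empty-vector libraries, a ratio of 76.7 with an exact 95% interval of 13.4 to 3066. The reads, 1.34 CPM, do not measure a transgene whose sequence differs from the gene's. TGM2 (ENSG00000198959, chromosome 20: 38127385 to 38166578), the transglutaminase that serotonylates histone H3, fell from 18890 ± 926 to 13660 ± 2809 normalised reads (SD, n = 3), a log2 change of -0.49 (SE 0.11, limma adjusted p = 0.0026).

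DDC cells lost RNA of epithelial and calprotectin genes and gained RNA of metallothioneins. S100A9, which with S100A8 forms calprotectin, fell from 3530 ± 406 to 73.9 ± 8.18 normalised reads (log2 -5.56, SE 0.10, limma adjusted p = 1.5e-21), and S100A8 fell by 4.72 on the log2 scale. Also among the largest falls were CYB5R2 (-5.75), the trypsinogen PRSS2 (-5.58), S100A14 (-4.89), the anchoring-filament gene LAD1 (-3.88), the cytochrome P450 CYP1B1 (-3.83) and the adhesion molecule MPZL2 (-3.77). Among the largest rises were AK5 (2.35), MT1X (2.09), the complement protease C1S (1.86), ALDH3A1 (1.62), MT2A (1.52), ID3 (1.31) and HTRA1 (1.25). The adjusted p of these genes ranged up to 2.2e-04, and for each all 3 libraries of one group lay above all 3 of the other.

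Of 10 measured luminal epithelial markers 9 fell with DDC, as they did adjusted over the list alone, with a median log2 change of -0.86. CDH1, which encodes E-cadherin, fell by 3.54 on the log2 scale, the claudin CLDN7 by 3.59, the epithelial splicing regulator ESRP1 by 3.27, EPCAM by 1.91 and KRT7 by 0.85, while CLDN3 (-0.31) did not pass. Camera gave this list an adjusted p of 2.3e-13, and an adjusted p = 0.0581 with an estimated correlation. Among 7 basal markers 3 fell (4 adjusted over the list alone), led by the integrin ITGB4 (-1.88), at an adjusted p of 0.00179 and an adjusted p = 0.150 with an estimated correlation. The endothelial gene PECAM1 (-1.49) and the fibroblast collagen COL1A1 (-1.64), the 2 measured genes of other cell types, fell as well.

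Genes of hypoxia and glycolysis fell: 7 of 12 were lower (9 adjusted over the list alone), among them BNIP3 (-0.92), PGK1 (-0.81) and LDHA (-0.80), with a camera adjusted p of 3.7e-06 and an adjusted p = 0.150 with an estimated correlation. In the unfolded protein response 4 of 12 fell (7 adjusted over the list alone), including the chaperones HSPA5 (-0.95) and HSP90B1 (-0.80), at 2.1e-04 and an adjusted p = 0.0862 with an estimated correlation. Of 13 NF-kB and cytokine genes 5 fell and 1 rose (5 and 4 adjusted over the list alone), with IL1B at -1.62, CXCL8 at -0.99 and CXCL1 at -0.96. That list's adjusted p was 0.0351, with an adjusted p = 0.207 with an estimated correlation and 0.0591 without empty-vector replicate 1, in a range of 0.00909 to 0.207 over the alternatives with camera; fry, which tests a list against no change and not against other genes, gave 0.00534. All 3 measured metallothioneins, near-identical metal-binding paralogs whose reads can be shared, rose (3 adjusted over the list alone), at 2.9e-08 and an adjusted p = 0.0862 with an estimated correlation.

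Proliferation genes moved little. Of 16 G1/S genes 3 rose (4 adjusted over the list alone), with MCM5 at 0.34 and CDT1 at 0.45, and of 15 G2/M genes 5 rose, with CCNB1 at 0.37 (8 rose and 1 fell adjusted over the list alone). The G1/S list had an adjusted p of 0.0351, which was 0.0564 without empty-vector replicate 1, 0.0586 without replicate 2 and adjusted p = 0.207 with an estimated correlation (camera range 0.0164 to 0.207; fry, against no change, 0.0127). The G2/M list had 0.0461, which was 0.0846 without DDC replicate 2, 0.0950 without empty-vector replicate 2, 0.0776 without replicate 3 and adjusted p = 0.207 with an estimated correlation (camera range 0.0198 to 0.207; fry, against no change, 0.00359), and 0.0722 with a replicate block. With scaling by library size alone the median of all genes lay at -0.12, and the rises of CDT1 and MCM5 no longer passed.

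The other 13 tested lists did not pass, with adjusted p from 0.0789 to 0.741. Of 18 neuroendocrine markers 4 were measurable: ENO2 fell by 0.42, and SCG5 (-0.49), DLL3 (0.33) and SYT1 (0.58) did not pass over all genes (1 rose and 1 fell adjusted over the list alone, list adjusted p = 0.741). None of 4 neural transcription factors passed (0 adjusted over the list alone). In tryptophan handling the kynurenine enzymes KYNU (-1.49), IDO1 (-1.17) and KMO (-1.15) fell; IDO1 did not pass without empty-vector replicate 2, nor KMO without DDC replicate 2 or empty-vector replicate 3. PMEPA1 fell (-1.08) in the androgen receptor program, and AXL rose (0.87) while TGFBI fell (-2.14) among mesenchymal markers. NQO1 (0.88) and TXNRD1 (0.74), NRF2 targets, rose. The lists' adjusted p were 0.493 for neural factors, 0.468 each for the androgen receptor program, mesenchymal markers, tryptophan handling and immediate early genes, 0.493 for transglutaminases with the H3K4 methylation machinery, 0.381 for cholesterol synthesis, 0.510 for ATF4, 0.741 for interferon, 0.115 for mitochondrial transcripts, and 0.0789 each for NRF2 and ribosomal proteins. Some of these passed in single alternatives: mitochondrial transcripts without DDC replicate 3 (9.7e-04) or empty-vector replicate 1 (0.0157; range 9.7e-04 to 0.602), NRF2 without DDC replicate 2 (0.0470) or with a replicate block (0.0491; camera range 0.0470 to 0.207; fry, against no change, 0.0116) and ribosomal proteins without DDC replicate 1 (0.0204; range 0.0204 to 0.602). The median, mean and test of the mesenchymal, interferon and neuroendocrine lists differed in sign.

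In all, 2281 of 13146 genes changed with DDC (1175 up and 1106 down, limma), 382 of them 2-fold (67 up and 315 down). The groups did not overlap in 4379 genes, 33.3%, where chance gives 10%. edgeR on the recovered reads called 2312 genes and DESeq2 1453, against 1470 in the deposited results. Scaling by library size alone in edgeR gave 593 up and 1801 down, or 24.8% up. With TMM scaling edgeR had 46.6% up, and limma had 51.5%, so directions are relative to the median gene.

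SLC6A4 overexpression was asked the same question. The SLC6A4 gene (ENSG00000108576, chromosome 17: 30194319 to 30236002) had 344 reads over its 3 libraries and 1 over the 3 empty-vector libraries, a ratio of 321 (exact 95% interval 57.3 to 12720). TGM2 rose from 19870 ± 934 to 32840 ± 521 normalised reads (SD, n = 3; log2 0.73, SE 0.05, limma adjusted p = 7.0e-09). PLAT, tissue plasminogen activator, and hair keratin genes rose: PLAT by 2.12, KRT34 by 2.59, and the near-identical keratin-associated genes KRTAP2-4 and KRTAP2-3 by 2.33 and 2.14. MAP7D3 (2.64) and CCN1 (1.62) rose too. S100A8 (-3.67), S100A9 (-3.63), PRSS2 (-3.80), the mucin MUC5AC (-3.73), and the protease inhibitors SERPINB11 (-4.57) and SERPINB4 (-4.18) fell. MSMP (-4.85) and RGP1 (-4.84) overlap and had nearly equal values, about 175600 against 6098 and 6109 normalised reads, so which of them fell is uncertain. The adjusted p of these genes, SLC6A4 included, ranged up to 3.2e-07, and in each all 3 libraries of one group lay above all 3 of the other.

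Cholesterol synthesis rose with SLC6A4: 12 of 14 measured genes (12 adjusted over the list alone) were higher, with a median log2 change of 1.01, among them FDFT1 (1.30), FDPS (1.24) and DHCR7 (1.01). Camera gave 4.6e-12, and an adjusted p = 0.0305 with an estimated correlation. Of 16 G1/S genes 9 rose (11 adjusted over the list alone), with RRM2 at 0.53 and MCM5 at 0.50, at an adjusted p of 3.0e-06. Of 15 G2/M genes 8 rose (11 adjusted over the list alone), with BIRC5 at 0.74 and TPX2 at 0.54, at 1.2e-07. In the unfolded protein response 6 of 12 fell (8 adjusted over the list alone), with HSP90B1 at -0.47 and HSPA5 at -0.40, at 1.9e-05. These last 3 lists each had an adjusted p = 0.0457 with an estimated correlation.

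Epithelial, hypoxia and cytokine genes fell with SLC6A4 as well, in lists whose calls were lost with an estimated correlation. Of 10 luminal markers 7 fell (8 fell and 1 rose adjusted over the list alone), with ESRP1 at -1.28, CDH1 at -1.17 and CLDN7 at -1.02, while CLDN3 (-1.75), KRT7 (0.19) and KRT8 (0.14) did not pass over all genes; camera gave 9.5e-04, and an adjusted p = 0.118 with an estimated correlation. Of 8 basal markers 4 fell (4 adjusted over the list alone), ITGB4 by 1.28, at 9.5e-04 and an adjusted p = 0.171 with an estimated correlation. Of 12 hypoxia and glycolysis genes 8 fell (8 adjusted over the list alone), with PGK1 at -0.88, BNIP3 at -0.79 and LDHA at -0.63, at 4.7e-06 and an adjusted p = 0.171 with an estimated correlation. Of 12 NF-kB and cytokine genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with CXCL3 at -1.96, IL1B at -1.83 and CXCL1 at -1.53, at 1.4e-05 and an adjusted p = 0.164 with an estimated correlation. MT1F (-1.23) and MT1X (-0.42), 2 of 3 metallothioneins (2 adjusted over the list alone), fell, and MT2A lay at -0.06; the list had 0.0163, and an adjusted p = 0.190 with an estimated correlation.

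The ATF4 and immediate early lists passed too, each lost in some alternatives. In the ATF4 list 2 of 14 fell (3 adjusted over the list alone), DDIT4 by 2.65 and ATF4 by 0.47, at an adjusted p of 0.0370, 0.0902 without SLC6A4 replicate 1, and adjusted p = 0.338 with an estimated correlation (range 0.0151 to 0.338). Among 8 immediate early genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), with FOS at -2.14 and FOSL1 at 0.36, at 0.0359, 0.0659 without SLC6A4 replicate 3, 0.0822 without empty-vector replicate 2, and adjusted p = 0.190 with an estimated correlation (camera range 0.0206 to 0.190; fry, against no change, 0.00314). The other 10 lists did not pass (adjusted p 0.0672 to 0.907), although mitochondrial transcripts did without SLC6A4 replicate 1 (0.0138) or empty-vector replicate 1 (0.0027; range 0.0027 to 0.627), and ribosomal proteins without empty-vector replicate 1 (0.0315) or 3 (0.0457; camera range 0.0315 to 0.340; fry, against no change, 0.0143). With fry, against no change, 3 more lists passed: mesenchymal markers (adjusted p = 8.4e-04), tryptophan handling (0.0143) and the androgen receptor program (0.0223). Of 10 measured mesenchymal markers 5 rose and 4 fell (5 and 4 adjusted over the list alone). The median, mean and test of the interferon and NRF2 lists differed in sign. Among 4 measurable neuroendocrine markers SCG5 rose (1.42), ENO2 fell (-0.79), and SYP (1.31) and DLL3 (0.18) did not pass over all genes (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.536). The proliferation factor FOXM1 rose by 0.51, AXL by 1.36, while FN1 (-1.84), KYNU (-2.02), IDO1 (-2.47), PECAM1 (-2.34) and COL1A1 (-0.99) fell.

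**Figure D1:**
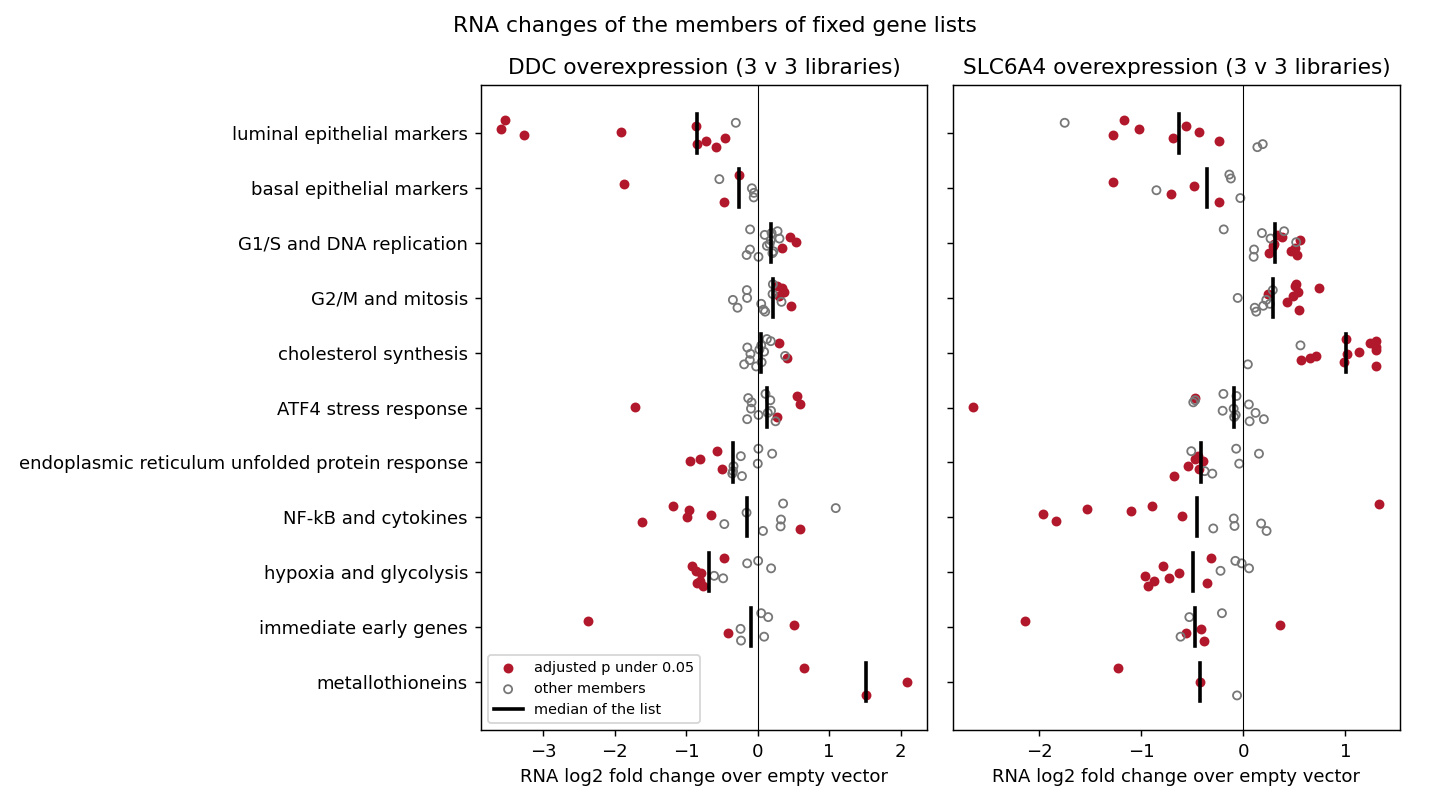
Log2 fold change of RNA over the empty vector for members of 11 gene lists with DDC (left) and SLC6A4 (right), 3 against 3 libraries; filled points passed an adjusted p of 0.05 over all genes and bars mark medians. Luminal markers had a median of -0.86 with DDC and -0.63 with SLC6A4, and cholesterol synthesis 0.05 and 1.01.

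In all, 2579 of 13264 genes changed with SLC6A4 (1348 up and 1231 down, limma), 420 of them 2-fold (115 up and 305 down). The groups did not overlap in 4629 genes, 34.9% where chance gives 10%. edgeR on the recovered reads called 2594 and DESeq2 1675, against 1686 in the deposited results. Scaling by library size alone in edgeR gave 1067 up and 1442 down, or 42.5% up. With TMM scaling edgeR had 48.9% up, and limma had 52.3%.

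Both lines lost many of the same genes. Both were at least 2-fold lower than the empty vector in 162 genes, S100A8, S100A9 and PRSS2 among them, and at least 2-fold higher in 18. Over 12939 genes tested in both, 553 rose in both and 592 fell in both, where independent lists would share 119 and 105, and 63 moved in opposite directions. The log2 fold changes correlated across genes, which are not independent replicates, with Pearson's r of 0.641 and Spearman's rho of 0.575. Unchanged groups sharing the same empty-vector libraries gave a rho of 0.462 in simulation. The covariance was 0.136 against 0.0219 simulated, a difference of 0.114.

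**Figure D2:**
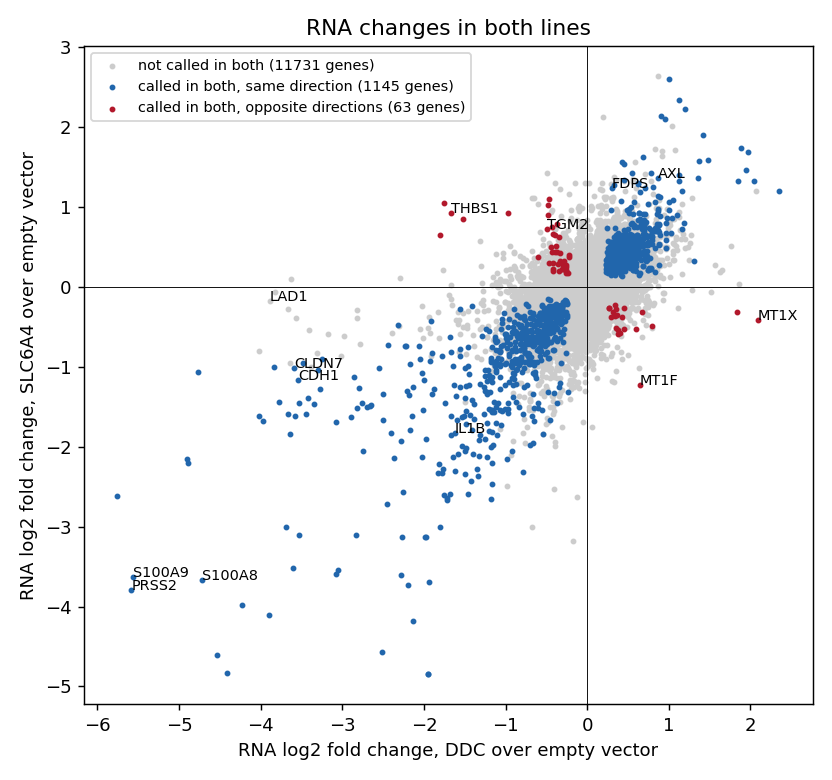
Log2 fold change of RNA over the empty vector with DDC (horizontal) against SLC6A4 (vertical), 1 point per gene tested in both. S100A9 lies at -5.56 and -3.63, MT1X at 2.09 and -0.42, and TGM2 at -0.49 and 0.73.

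The direct comparison of the lines asked where DDC and SLC6A4 differ. TGM2 was lower in DDC than in SLC6A4 cells (log2 -1.22, SE 0.10, limma adjusted p = 2.6e-08), having fallen in the former and risen in the latter. Metallothioneins were higher in DDC cells: MT1X by 2.51, MT1F by 1.87 and MT2A by 1.58, 3 of 4 measured (3 adjusted over the list alone), at a camera adjusted p of 1.2e-09 and an adjusted p = 0.00625 with an estimated correlation. The granulocyte factor CSF3 (3.00), C1S (1.83) and HEPHL1 (1.63) were also higher in DDC cells, as were the overlapping MSMP and RGP1 (both 2.90). CYP1B1 (-3.77), LAD1 (-3.71), the matrix proteins THBS1 (-2.58) and EFEMP1 (-2.45), CLDN7 (-2.58), the protease ST14 (-2.52) and FSIP1 (-2.38) were lower. The adjusted p of these genes ranged up to 2.9e-04.

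Cholesterol synthesis was lower in DDC than in SLC6A4 cells in 10 of 14 genes (11 adjusted over the list alone; camera 4.5e-13, adjusted p = 0.0039 with an estimated correlation), with FDFT1 at -1.12 and FDPS at -0.94. Luminal markers were lower in 6 of 8 (7 adjusted over the list alone; 1.8e-09, adjusted p = 0.00625 with an estimated correlation), and G2/M genes in 6 of 15 (9 adjusted over the list alone; 2.5e-04, adjusted p = 0.0256 with an estimated correlation). Of 16 G1/S genes 3 were lower (3 adjusted over the list alone; 0.0125, adjusted p = 0.0688 with an estimated correlation). ATF4 genes were higher in 7 of 14 (7 adjusted over the list alone; 3.6e-04, adjusted p = 0.0606 with an estimated correlation) and NRF2 genes higher in 4 and lower in 1 of 13 (the same adjusted over the list alone; 0.00525, adjusted p = 0.0606 with an estimated correlation). Of 13 cytokine genes 6 were higher, CXCL3 by 1.30, and 3 lower (7 and 3 adjusted over the list alone; 0.0140, adjusted p = 0.265 with an estimated correlation). The neuroendocrine gene SCG5 was lower (-1.91) and ENO2 higher (0.36), the latter not passing without DDC replicate 2 or SLC6A4 replicate 1. In all, 1766 of 12934 genes differed (874 higher and 892 lower in DDC cells), 259 of them 2-fold (100 and 159), with 3774 genes, 29.2%, not overlapping where chance gives 10%. edgeR called 1812 and DESeq2 1120.

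With DDC, H3K4me3Q5ser fell at or near the starts of several epithelial genes whose RNA had fallen, though of 11 luminal marker genes with a region 5 were lower and 4 higher, with a median of 0.04. At the LAD1 promoter (chromosome 1: 201397318 to 201400029) it fell from 24.3 ± 1.46 (SD, n = 2) to 7.60 ± 0.51 CPM (SD, n = 3), a log2 change of -1.70 (SE 0.07, edgeR adjusted p = 1.2e-39, both from 3 against 3 libraries). It fell by 2.06 at ST14, 1.40 at MPZL2, 1.18 at CDH1, 0.77 at KRT7 and 0.41 at ITGB4, and by 0.71 within 1000 bp of the start of TGM2. Cytokine promoters fell as well, CXCL1 by 0.67 and IL1B by 0.42; of 12 cytokine genes with a region 8 were lower and 2 higher. At 16 of 17 ribosomal protein genes with a region the mark rose, with a median of 0.18, and ENO2's promoter rose by 0.17. Falls of smallest adjusted p were a region in HIF1A on chromosome 14 (61744702 to 61753341, -1.02) and a region in JMJD1C on chromosome 10 (63260787 to 63271322, -0.48). Intergenic regions nearest DCBLD2 on chromosome 3 (-1.14 and -0.94) were the others. Rises of smallest adjusted p were at starts of EEF1G (0.20), DPF3 (0.35), NRP1 (0.16) and FUT11 (0.10). The EEF1G region is 119521 bp long and also overlaps other genes, so its change is not that of 1 promoter.

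H3K4me3Q5ser changed with DDC at 11924 of 19530 regions (5783 up and 6141 down, edgeR), 361 of them 2-fold (14 up and 347 down). TMM scaling removes any change common to all regions, and no spike-in of outside chromatin is named. Directions in all ChIP comparisons are therefore relative to the typical region, and a change in a mark's total amount cannot be read from them. The DDC libraries held 13.5 M to 16.7 M read pairs in the regions against 24.1 M to 24.4 M for the empty vector, whose effect was not tested. Several replicate libraries differed by no more than sampling noise (ratios of spread to noise 0.992 to 1.14 over the ChIP pairs), so p-values rest on little more than counting noise and small changes pass.

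With SLC6A4, H3K4me3Q5ser followed the GC content of regions, which accounted for 52.7% of the variance of its log2 fold change. The region at the start of CPSF1 on chromosome 8 (144401233 to 144465690) went from 651.2 ± 3.71 to 1031 ± 5.95 CPM (SD, n = 2). Its log2 change had an SE of 0.0050 and an edgeR adjusted p = 4.7e-175, both from 3 against 3 libraries. Starts in GC-rich stretches rose, as at CPSF1 (0.72), EXOSC4 (0.65), ARF1 (0.65) and EEF1G (0.33). With the GC trend of each library removed these were 0.24, 0.24, 0.36 and 0.13. The CPSF1 and EEF1G regions, 64458 and 119521 bp long, also overlap other genes. Falls were at EPC1 (-1.30, and -0.42 with the trend removed), the histone gene H3C4 (-0.47, and -0.10), SUCO (-0.64) and the JMJD1C region (-0.98). With the trend removed SUCO lay at -0.0027 (adjusted p = 0.798) and the JMJD1C region at 0.01 (adjusted p = 0.114). Some promoters of epithelial and cytokine genes fell also with the trend removed: MPZL2 by 1.14 (then -1.09), CXCL1 by 0.76 (then -0.64), EPCAM by 0.51 (then -0.39), CDH1 by 0.45 (then -0.97) and LAD1 by 0.37 (then -0.84). Before the trend was removed, of 11 luminal marker genes with a region 7 were higher and 4 lower (median 0.32), and of 12 cytokine genes 3 were higher and 6 lower (median -0.12). TGM2's start region rose by 0.20, and lay at -0.06 with the trend removed (adjusted p = 0.141). The mark changed at 16144 of 19535 regions (8081 up and 8063 down), 1990 of them 2-fold (525 up and 1465 down); with the trend removed 14506 changed and 481 did 2-fold.

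H3K4me3 with DDC changed less. It rose by 0.52 in a region at ZNF530 on chromosome 19 (57588767 to 57627739) and by 0.31 at ZNF248, and at NBPF1 (0.39) and a region in CUL2 (0.39). It fell at TSC22D2 (-0.35, and -0.70 at an intergenic region near it), the HIF1A region (-0.42) and an intergenic region near DPYD (-0.64). ZNF530's region went from 205.3 ± 8.41 to 293.3 ± 6.30 CPM (SD, n = 2; SE 0.04, edgeR adjusted p = 3.7e-37). At epithelial promoters it fell by 0.48 at LAD1, 0.40 at ITGB4 and 0.32 at MPZL2, while CDH1 (-0.13) and ST14 (-0.36) did not pass. It changed at 3325 of 18650 regions (1579 up and 1746 down), 54 of them 2-fold (25 up and 29 down); DESeq2 called 1341, of which 16 were 2-fold.

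H3K4me3 with SLC6A4 rose in regions at 3 zinc-finger genes. ZNF530's region went from 205.3 ± 8.41 to 467.7 ± 1.15 CPM (SD, n = 2). It rose by 1.16 on the log2 scale (SE 0.03, edgeR adjusted p = 9.4e-271, both from 3 against 3 libraries). ZNF550 rose by 1.05 and ZNF17 by 1.04, and the 3 were 1.22, 1.06 and 1.06 with the GC trend removed. CPSF1 rose by 0.59 (then 0.10). Falls were at SEMA3A (-1.21, then -0.38), EPC1 (-0.96, then -0.32), a region near IFNE (-0.93, then -0.31) and the JMJD1C region (-0.89, then -0.16). CXCL1's promoter fell by 0.73 (then -0.69). It changed at 11637 of 18805 regions (5896 up and 5741 down), 1073 of them 2-fold (436 up and 637 down), with 44.8% of the variance following GC content; with the trend removed 7974 changed and 451 did 2-fold.

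Whether the serotonylated mark changed beyond H3K4me3 was tested as an interaction. The marks' changes correlated across regions, which are not independent replicates, at r of 0.579 with DDC and 0.836 with SLC6A4. With SLC6A4, GC content accounted for 52.7% of the variance of the H3K4me3Q5ser change and 44.8% of the H3K4me3 change, which may raise that r. Neither these correlations nor the interactions were recomputed with the GC trend removed. At the start of ESRP1 (chromosome 8: 94638636 to 94641708), whose RNA fell by 3.27 on the log2 scale with DDC, H3K4me3Q5ser fell relative to H3K4me3 by 1.63 (SE 0.12, edgeR adjusted p = 3.5e-32). It fell relative to H3K4me3 in CYP1B1 (-1.34), at a start of ANK3 (-0.97) and near DCBLD2 (-0.74), and rose relative to it at POLR2J3 (0.55), CAMK2G (0.45), CPSF1 (0.25) and EEF1G (0.18). With DDC 2889 of 19495 regions differed (1025 up and 1864 down), 122 of them 2-fold (31 and 91); leaving out any 1 library number left 1608 to 1908. With SLC6A4 the mark fell relative to H3K4me3 within TMPRSS2 (-1.54), within ZNF615 (-1.20) and at ESRP1 (-1.18). In these regions H3K4me3Q5ser itself changed by -0.55, -0.34 and -0.48, and H3K4me3 by 0.97, 0.85 and 0.68. The serotonylated mark rose relative to H3K4me3 at TSC22D2 (0.47), NRP1 (0.41), DKK1 (0.37) and VARS1 (0.30). At TSC22D2, NRP1 and DKK1 H3K4me3Q5ser itself changed by -0.16, 0.01 and -0.05, and H3K4me3 by -0.645, -0.41 and -0.43. The difference at these came mostly from H3K4me3. At VARS1, a region of 66425 bp that also overlaps other genes, the marks changed by 0.41 and 0.10. In the SLC6A4 interaction 5755 of 19534 regions differed (2855 up and 2900 down), 311 of them 2-fold (27 and 284). Scaling by library size alone gave 6130, of which 23.4% were up in place of 49.6%, with a median of -0.10.

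Losses of H3K4me3Q5ser were shared between the lines, as at the promoter of MPZL2 (-1.40 with DDC and -1.14 with SLC6A4): 249 regions were 2-fold lower in both lines and 4 higher in both. With the GC trend of each library removed, a test chosen after seeing the data, 64 were lower and 7 higher in both, so most of the 249 did not remain. Its log2 fold changes correlated across regions, which are not independent replicates, at r of 0.569 (0.638 with the trend removed), with a covariance of 0.118 against 0.0027 from the shared empty-vector libraries. For H3K4me3, 13 regions were 2-fold lower and 12 higher in both (6 and 21 with the trend removed), with r of 0.382 (then 0.612) and a covariance of 0.0480 against 0.0114.

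The marks were then set against RNA across genes, which are not independent replicates. With DDC the promoter change of H3K4me3Q5ser correlated with the RNA change at a Spearman rho of 0.304 over 11055 genes, and that of H3K4me3 at 0.143. With the GC trend of each library removed these were 0.265 and 0.185, a smaller gap. H3K4me3 had fewer read pairs, whose effect on its rho was not tested. Across genomic bins the DDC changes of RNA, H3K4me3Q5ser and H3K4me3 followed the DDC input ratio, at r of 0.827, 0.925 and 0.707. The rho values were not recomputed with that ratio removed, so part of them may reflect it. The 181 genes with a region whose RNA fell 2-fold had a median H3K4me3Q5ser change of -0.37, lower in 85.1% of them, and a median H3K4me3 change of -0.13. With SLC6A4 rho was 0.132 and 0.112, and the 179 genes that fell had medians of -0.14 and -0.04, where genes not called had 0.12 and 0.06. With the GC trend removed these were -0.09 and -0.13, against 0.14 and -0.0074 in genes not called. With DDC the medians of genes that fell were -0.36 and -0.11 with the trend removed.

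Genes at H3K4me3Q5ser regions were compared with genes at H3K4me3 regions alone, by draws matched on expression and by camera over all of them without matching. With DDC the 46 genes with H3K4me3 alone had a median RNA change of -0.16, which lay at percentile 0.97 of the medians of 10000 matched draws from 11055 genes at H3K4me3Q5ser; the mean of these medians lay 0.172 higher (camera p = 0.0186, two-sided; p = 0.0509 with an estimated correlation). Without DDC replicate 2 the difference was 0.107 and did not pass (limma's camera), in a range of 0.107 to 0.207 over the libraries left out. With SLC6A4 the difference from the matched draws was 0.0469 for 48 genes, at percentile 19.7 and so within the draws, with camera p = 0.00415 (p = 0.0268 with an estimated correlation). It was 0.186 without empty-vector replicate 2, 0.108, 0.0907 and 0.0749 without SLC6A4 replicates 1, 2 and 3, 0.0620 and 0.0716 without empty-vector replicates 1 and 3, and 0.0072 (percentile 43.9 of the draws) with regions taken within 3000 bp of the start, so its size is not settled.

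The peak lists of the marks overlapped. Of 19535 H3K4me3Q5ser peaks 12439 overlapped an H3K4me3 peak, 63.7% (Wilson 95% interval 63.0% to 64.3%), and of 26514 H3K4me3 peaks 20847 overlapped an H3K4me3Q5ser peak (78.6%). H3K4me3Q5ser peaks were the longer, with a median of 4022 bp against 779 bp, and 9.07% overlapped under a stricter reciprocal rule.

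CUT&Tag peaks of H3K4me3 listed by the authors as up, 2163 of them, lay at genes that include the histone methyltransferases KMT2A, KMT2B, KMT2D and SETD1A, the demethylases KDM5A, KDM5B and KDM5C, the mitotic genes CCNB1, AURKA and TOP2A, the plasticity factors EZH2 and FOXM1, and AXL. Such a peak was held by 8 of 21 genes of transglutaminases and the H3K4 methylation machinery and 6 of 12 of the unfolded protein response. It was held by 6 of 18 of ribosomal proteins, 5 of 15 of mitosis and 4 of 14 immediate early genes. None was held in the neuroendocrine, androgen receptor, luminal, basal, tryptophan handling, interferon, NF-kB, NRF2 and metallothionein lists. Over the genes tested with DDC, 1922 lay at an up peak and 7546 only at other listed CUT&Tag peaks. These shares were not tested, so no list is read as marked out. All 2163 up peaks and 13848 of 13882 others overlapped an H3K4me3Q5ser peak by at least 1 bp (Fisher's exact test, two-sided, p = 0.0110, lower bound of the odds ratio 1.36, with peaks that are not independent replicates). Under a reciprocal rule 24 and 791 did, 1.11% against 5.70%, so the direction depends on the rule and no link with H3K4me3Q5ser is read from it. All 2163 and 13882 have the same coordinates as peaks of the H3K4me3 ChIP list, so their overlap with that list is no comparison of the assays. RNA of genes at up peaks was not found to differ from that of genes at other CUT&Tag peaks, as neither line passed limma's camera (two-sided). The difference of medians was 0.010 with DDC over 1922 genes (0.0022 to 0.0176 with a library left out) and 0.027 with SLC6A4 over 1926 genes (0.0236 to 0.0289).

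Values per library were given for the 13882 peaks not listed as up. There H3K4me3 in SLC6A4 cells lay at a median log2 ratio of 0.10 to control cells, and with TGM2 knocked down at -0.083 to SLC6A4 cells and 0.012 to control cells. With 1 library each these differences have no replicate check. Scaled to the sum over these peaks they were -0.0256, -0.0093 and -0.0427, so the sign of both ratios to control cells depends on the scaling and no rise or fall is read from them. The highest ratio of SLC6A4 to control was 1.25, so peaks above it are absent and the medians describe peaks selected on that ratio. The listed peaks summed to 34.3%, 37.5% and 35.6% of the control, SLC6A4 and knockdown libraries.

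**Figure D3:**
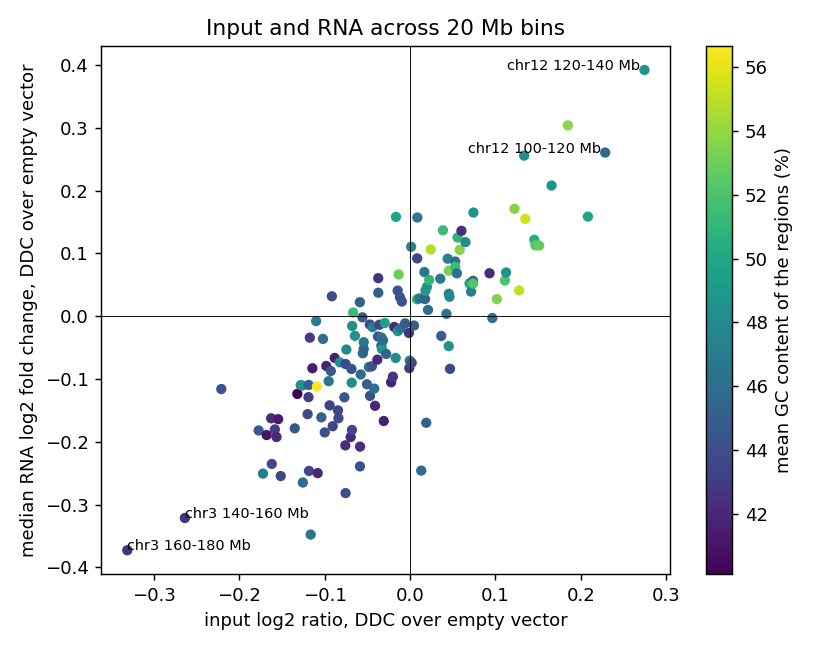
Log2 ratio of ChIP input reads within H3K4me3Q5ser regions, DDC over empty vector, summed in bins of 20 Mb (GRCh38). It is set against the median log2 fold change of RNA with DDC in the same bins. The ratio ranged from -0.33 to 0.27 over 154 bins.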

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

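The differences between the lines were tested as planned. Chosen after the results were seen were the tests of the regroupings of the overlap, shared controls, other cell types, extra RNA, read depth, counting noise and GC content as the whole cause, and the splits of the RNA and ChIP counts; the tests of GC bias, transcription, copy number and GC content of the input were written before.

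RNA of 6 named genes moved in opposite directions in the lines, with a test of the difference itself. THBS1 fell by 1.66 on the log2 scale with DDC and rose by 0.92 with SLC6A4 (difference -2.58, limma adjusted p = 9.4e-16). MT1X rose by 2.09 and fell by 0.42 (difference 2.51, adjusted p = 6.6e-15), and MT1F rose by 0.64 and fell by 1.23 (1.87, adjusted p = 1.8e-09). FSIP1, which overlaps THBS1 on chromosome 15 so that reads can be shared, had -1.52 and 0.85 (-2.38, adjusted p = 7.6e-11), EFEMP1 -1.80 and 0.64 (-2.45, adjusted p = 3.6e-07) and TGM2 -0.49 and 0.73 (-1.22, adjusted p = 2.6e-08). In each all 3 libraries of one line lay above all 3 of the other.

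Genes lower in both lines than in the empty vector, 162 of them 2-fold and S100A9 and PRSS2 among them, were weighed first. The covariance of the lines' log2 fold changes was 0.136, above the highest of 50 simulations of shared controls (0.0232), which argues against chance values of the shared libraries. Marker genes were summed by cell type (blood, fibroblasts, endothelium) in each empty-vector library and the second lowest library taken; the highest such value was 11.5 CPM, for endothelium. It rested on PECAM1 (mean 11.84 CPM) with VWF and CDH5 at 0, which argues against RNA of those cells; the bound, first set at under 10 CPM, was widened after the sum was seen. HBB, at 489 reads in empty-vector replicate 2 and 0 in the other empty-vector libraries, lies outside that bound. Against extra RNA with no difference in the cells, the 76 of these genes with a region had a median H3K4me3 change with DDC 0.137 below matched genes (-0.137), and an H3K4me3Q5ser change with SLC6A4, GC trend removed, 0.357 below (-0.357). A first form of that test, H3K4me3 in both lines, was undecided and was replaced (SLC6A4 -0.0847, percentile 6.57; -0.163 with the GC trend removed). A test of culture density, with 0 of these genes in the hypoxia list, was dropped. What stays open is that a single empty-vector line serves both comparisons, so a trait of that line may account for a pattern with a covariance of 0.136.

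Changes of both marks with SLC6A4 were weighed next. GC content accounted for 52.7% of the variance of the H3K4me3Q5ser change, so GC bias of the libraries may explain a large part of it, although 14506 regions changed after the trend was removed. H3K4me3Q5ser read pairs were 0.919 of the empty vector's, which argues against fewer reads as the cause for that mark with SLC6A4. No such test was made with DDC, where its libraries held 13.5 M to 16.7 M read pairs against 24.1 M to 24.4 M. H3K4me3 had more read pairs with SLC6A4 (4.74 M to 5.81 M against 3.43 M to 4.34 M), whose effect was not tested. A difference of transcription cannot be told apart: the rho of 0.129 between mark and RNA lies between the bounds set beforehand.

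ChIP input, used in no comparison, was counted within the 19535 H3K4me3Q5ser regions only and summed over those in each bin of 20 Mb. It shifted between DDC and empty-vector cells: 104 of 154 bins lay beyond 3 counting standard errors, 67.5%, which argues against counting noise. The ratio was lowest on chromosome 3 from 160 to 180 Mb (-0.33, RNA -0.37) and highest on chromosome 12 from 120 to 140 Mb (0.27, RNA 0.39). Over 150 bins, which are not independent replicates, it followed the median RNA change with DDC at r of 0.827 and rho of 0.820 (permutation p = 1e-05 for each, two-sided, the smallest that 100000 permutations can give), and at r of 0.804 without the 2 bins farthest out. A difference of DNA copy number between the lines is a candidate explanation. It was not measured directly, since the input reads come from the mark's regions, 9013 of them at a transcription start, and not from whole bins. GC content of the input fits in part (r of 0.544), but as the whole cause it is argued against by r of 0.745 with GC trends removed from both. With the ratio of its bin removed from each gene, 1799 genes changed with DDC, 1600 of them among the 2281. Copy number therefore may contribute to the DDC changes of RNA and marks (r of 0.925 with H3K4me3Q5ser). The DDC input ratio followed SLC6A4 changes too, at r of 0.366 for RNA (0.278 with GC trends removed), 0.588 for H3K4me3Q5ser and 0.629 for H3K4me3 (not recomputed so), and part of the shift may lie in the empty-vector cells that both comparisons share.

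Splits of 3 against 3 libraries number 10, too few for a share under 0.05; in all but 1 of these results, 1 split, the real one, reached the real value. The real count and the highest other split were 2281 and 1 genes for DDC, 2579 and 1 for SLC6A4, 1766 and 1 for DDC against SLC6A4, and 8 and 3, and 11 and 8, for lists with DDC and SLC6A4. For H3K4me3Q5ser they were 11924 and 0 with DDC and 16144 and 0 with SLC6A4, for H3K4me3 3325 and 0, and 11637 and 0, and for the mark relative to H3K4me3 2889 and 0, and 5755 and 0 (edgeR). For RNA at H3K4me3Q5ser regions they were 0.172 and 0.165 with DDC, and 0.0469 and 0.131 with SLC6A4, where 6 of 10 splits reached the real value; for RNA at CUT&Tag up peaks 0.010 and 0.00882, and 0.0266 and 0.0116. Of 100 regroupings of the 9 libraries, scaled together, only the real one gave 1136 shared calls (highest other 234). The count was 1145 where each comparison is scaled by itself. Regroupings mix lines that already lay apart in RNA, so this shows only that the 9 libraries are not interchangeable. It cannot exclude a chance trait of the single empty-vector line.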

How the results depend on the processing

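Chosen after the results were seen were the tests with GC or input removal, edgeR on recovered reads, other pseudocounts, the CUT&Tag scaling, and the block and left-out libraries for lists, overlap and RNA at marked genes. Of values recomputed under alternatives, 187 of 202 for comparisons kept their size, or their direction and side of the threshold. So did 3292 of 3407 for named genes, 492 of 496 for named regions, 423 of 462 for lists and 111 of 122 2-fold counts. A count was taken to keep its size within a fixed ratio of the main count, which is a wide bound. For RNA with DDC, 1609 genes without empty-vector replicate 2 counted as kept against 2281, while DESeq2's 1453 did not. For counts only the number called was judged and not its split into up and down. That split moved with scaling by library size alone: for RNA with DDC, edgeR then had 24.8% up, against 46.6% with TMM. DESeq2 called fewer: 1453 genes with DDC, 1675 with SLC6A4, 1120 between the lines, 721 shared calls and 1341 H3K4me3 regions with DDC. With an estimated correlation 0 lists passed with DDC and 4 with SLC6A4 (camera; 8 and 11 at the preset correlation), and RNA at H3K4me3Q5ser with DDC had 0.170 (p = 0.0509). Shared calls of at least 2-fold numbered 180. Leaving out libraries gave 1608 to 1908 regions for the DDC interaction and 0.107 to 0.207 for RNA at H3K4me3Q5ser with DDC; where 1 library remained apart, the fit pools the spread. A reciprocal rule on both peaks gave an overlap of 9.07%, as H3K4me3 peaks are far shorter, and CUT&Tag scaled to the listed peaks -0.0093. The JMJD1C region with SLC6A4 reversed with the GC trend removed, to 0.0111, and 0.0107 with a replicate block too. Beyond the peak overlap, the cause was not tested. Same-number libraries of different groups correlated at -0.0769 to 0.00845 in RNA (9 pairs) and -0.0302 to 0.0438 in ChIP (45 pairs), with 0 over 0.1. A replicate block gave 2369, 2497 and 1696 genes, 1131 shared calls, 8 and 11 lists, 11749, 16136, 3376 and 11620 regions, 2851 and 5679 for the interactions, 0.170 and 0.0472 for RNA at H3K4me3Q5ser, and 0.0722 for the G2/M list with DDC. Not run were peak score thresholds, since the lists carry no scores, and CUT&Tag TMM, left-out libraries and blocks, with 1 library per group. No paired analysis was possible because peak lists and CUT&Tag groups hold 1 set of values each. Depth limits H3K4me3, at 3.43 M to 5.81 M read pairs, more than H3K4me3Q5ser.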

Other observations

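The genes here were picked after their values were seen because they moved in opposite directions in the lines; no group of genes was tested. The mitochondrial chaperone HSPD1 fell by 0.42 on the log2 scale with DDC and rose by 0.29 with SLC6A4 (difference -0.72, limma adjusted p = 4.4e-07), and its partner HSPE1 had -0.30 and 0.23 (difference -0.53). The chaperonin subunits CCT4 (-0.26 and 0.21) and CCT8 (-0.26 and 0.20) and the heat shock protein HSP90AA1 (-0.39 and 0.43) did likewise. The desaturase SCD, which makes monounsaturated fatty acids, had -0.43 and 0.75, and the caveolar protein CAV1 -0.47 and 0.30, while the growth factor MDK rose by 0.79 with DDC and fell by 0.49 with SLC6A4.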
